A study of Mus musculus with 45 samples.

How the data were processed

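RNA was sequenced from the distal colon of wild-type mice and of mice lacking Il10, the gene for the anti-inflammatory cytokine interleukin 10. Mice without this gene develop colitis, and the strain is a common model of inflammatory bowel disease. Per the labels, messenger RNA libraries were made by poly(A) enrichment from column-purified RNA. The 45 libraries fell into 6 labelled groups. In the first cohort these were 8 untreated wild-type libraries, 10 knockout libraries given vehicle, 9 given compound 13 at 30 mg/kg and 7 given compound 13 at 10 mg/kg. Compound 13 is the code name of a selective antagonist of GPR4, a receptor that senses extracellular protons. A second knockout cohort, labelled day 77, held 5 vehicle libraries and 5 libraries from mice given an antibody to p40, the protein subunit shared by interleukins 12 and 23. The labels of 1 further library disagreed, with 30 mg/kg in its title and 10 mg/kg in its treatment field. It entered no comparison. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. They give no sex, age, cage, litter or sequencing batch, and replicate numbers follow the deposited order and pair nothing.

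The submitters' processing notes list cutadapt 3.7, STAR 2.7.8a, RSEM 1.3.3, DESeq2 1.30.1 and the mouse build mm10 without saying what each was used for. The gene annotation, the strandedness of the library kit and the treatment of multiply mapped reads were not given in the sources used here. The authors deposited estimated counts per gene for both cohorts, not normalized, of which 17.1% of the values above 0 in the first cohort and 20.4% in the day 77 cohort were not whole numbers. The authors also deposited TPM, a transcript abundance corrected for length and depth, for the same libraries and genes, scaled by them to the same total in each library. For 4 comparisons the authors deposited, per the file headers, a log2 fold change of the first named group over the second. Beside it, per the file headers, stood a Wald test p-value and its Benjamini-Hochberg adjusted p-value, together with a significance flag. Their design and covariates, and which libraries entered them, were not given in the sources used here. Values from these tables are named as the authors'.

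The count tables held 50600 gene identifiers, of which 50376 matched the GENCODE M21 annotation of GRCm38 (mm10), the source of symbols, gene types and coordinates, and 224 did not match. The total count per library was 22682495 to 26410890 in wild type, 23215070 to 27824904 in knockout vehicle, 24712551 to 31007363 at 30 mg/kg and 23572560 to 35439633 at 10 mg/kg. It was 23631588 to 36279786 in day 77 vehicle, 24346127 to 32054882 with anti-p40 and 35001103 in the unassigned library. A gene with 0 counts in the shallowest knockout library could still hold 0.129 CPM (counts relative to the total count of the library), taking 3 counts as the limit that 0 allows. Such limits, and intervals made from counts, cover counting error only. No pair of libraries within a group agreed within sampling noise. The lowest chi-square per degree of freedom over pairs was 8.12, so each library counted as 1 replicate.

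Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood fit with robust estimates, TMM scaling, its default expression filter) under R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The knockout and anti-p40 comparisons were fitted with only their own groups. The compound 13 comparisons shared one fit of the 3 knockout groups of the first cohort. The difference between the anti-p40 effect and the 30 mg/kg effect was tested in one fit of all 6 groups, in which each treatment was set against the vehicle of its own cohort. Unless another tool is named, adjusted p-values of genes are from edgeR. CPM of named genes are scaled by TMM within each fit, so that the same group can have slightly different values in different comparisons. In the plot of receptors, CPM are scaled by TMM over all 45 libraries, and in that of acinar genes to the total count. Gene values are given as mean ± SD and log2 fold changes as estimate ± SE.

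A score was made for each of 29 gene lists (cell type markers, cytokine responses and pathways of the colon) as the mean log2(CPM + 1) over the tested members in each library. Group differences were tested by two-sided exact permutation of the library labels, over 43758 arrangements for 10 against 8 libraries, 92378 for 9 against 10, 19448 for 7 against 10 and 252 for 5 against 5. The smallest p that 5 against 5 can give is 0.00794. These p-values were adjusted over the 29 lists of a comparison, and 95% intervals came from 10000 bootstrap resamples. A list test says whether a list differed between groups, not whether it did so more than other genes. Called members are counted over all genes tested and again when adjusted over the list alone.

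A disease score used the genes called between knockout vehicle and wild type at an absolute log2 fold change of at least 1, as the mean of the higher genes minus that of the lower genes. For compound 13, the 10 vehicle libraries were split 20 times into sets of 5, with the signature taken from one set and the score compared with the other, because shared libraries would otherwise lower the score by chance. An anti-p40 score was built in the same way from all genes called between anti-p40 and day 77 vehicle. Effects were also correlated across genes, which are not independent replicates.

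The gene tests of 5 comparisons and the exact permutation test were run on simulated data, while the test between doses, the family tests and the bootstrap intervals were not. Counts were drawn from the libraries' own means and spreads with 200 changed genes. These were taken only from genes above a minimum mean count. The recovered shares therefore do not apply to genes of low counts, Gpr4, Il12a and Il12b among them. These shares also hold only with 200 changed genes, because the adjusted p of a gene depends on how many other genes change. For 30 mg/kg against vehicle, where the smallest adjusted p in the real data was 0.61, they may therefore be too high. At a 2-fold change the recovered share was 85.1% for the knockout comparison (16435 genes), 80.6% for 30 mg/kg and 77.6% for 10 mg/kg against vehicle (16948 genes), 68.7% for anti-p40 (16470 genes) and 64.2% for the difference between treatment effects (18021 genes). At a 1.5-fold change it was 53.7%, 59.7%, 58.2%, 25.4% and 13.4%.

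The comparisons, tests, gene lists, scores and most alternatives were fixed before the data were examined, as was the rule for the genes the text names. The rule took Il10, proton-sensing receptors such as Gpr4, Gpr65 and Gpr132, and the cytokine genes Il12a, Il12b and Il23a in every comparison. It added the 5 protein-coding genes with the largest rise and the 5 with the largest fall among called genes at a mean of at least 1 CPM, and the 2 members with the smallest adjusted p of the 8 lists with the largest score differences. Where fewer than 5 genes passed, it took the 5 genes with the smallest p. Some genes that the rule took are not reported here, although list scores and counts of called genes include them. The alternatives were other size factors, DESeq2 1.42.0, other expression filters, leaving out immunoglobulin and mitochondrial genes, limma 3.58.1 with voom and sample weights or on log2 of the TPM (pseudocounts 1 and 0.1, minimum TPM 1 or none), other groups in the fit, the unassigned library at either dose, medians in place of means, and each library left out in turn. Leaving out libraries that carried pancreatic RNA (at least 500 CPM of acinar genes) or had low complexity (under 19000 genes detected after thinning to 22682495 counts) was chosen after seeing the data, as was a list of 14 pancreatic acinar genes, picked after these genes were seen to separate libraries. Scores, permutation tests and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes that share reads with near-identical relatives (the Reg3, Gbp, Clca4, Gsdmc, Ces2, Cyp2c, S100a and immunoglobulin families) or with an overlapping gene are uncertain, because reads could be split between them.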

Results

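Gene expression was measured by RNA sequencing in the mouse distal colon, in wild-type mice and in mice lacking Il10. The latter were left with vehicle, given compound 13 at 10 or 30 mg/kg, or given an antibody to p40 in a cohort labelled day 77. The data held 45 libraries with 22682495 to 36279786 counts each, and 44 of them could be placed in a group. In total, 8 wild-type, 10 knockout vehicle, 9 knockout 30 mg/kg and 7 knockout 10 mg/kg libraries made up the first cohort, and 5 vehicle and 5 anti-p40 libraries made up the day 77 cohort. Coordinates are those of GRCm38 (mm10).

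Il10 (chromosome 1, 131019845 to 131024974) was looked at first, as it is the deleted gene. Wild-type colon held 10 Il10 counts over its 8 libraries, or 0.0496 ± 0.069 CPM (mean ± SD, n = 8), and no library exceeded 0.161 CPM. All 37 knockout libraries held 0 counts, which over their summed depth allows at most 0.00294 CPM. Taking 3 counts over the group as the floor, Il10 was at least 4.32-fold lower in knockout vehicle than in wild type. Expression in wild type was too low for a single knockout library, where 0 counts allow up to 0.129 CPM, to be told from wild type by this gene.

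The first comparison asked how the colon of vehicle-treated knockout mice differed from that of wild-type mice. The wild-type mice were untreated, so effects of the deletion and of the vehicle cannot be told apart here. Genes induced by interferon gamma, genes with which the gut epithelium answers interleukins 22 and 17, and markers of neutrophils, T cells, plasma cells and macrophages rose in the knockout colon. Smooth muscle, enteric nerve and glia, and collagen genes fell. Among the genes with the largest rises were Clca4b, a member of the calcium-activated chloride channel regulator family, and Reg3g and Reg3b, which encode antimicrobial lectins of the gut epithelium. Galnt17, a glycosyltransferase, was among those with the largest falls. In edgeR, 4147 genes were higher and 3965 lower in the knockout, or 8112 of 16435 tested, and 1195 of the higher and 977 of the lower genes changed at least 2-fold. With limma on log2(TPM + 1), where the test, the filter (14657 genes) and the scaling all differed, the median log2 fold change was -0.17 in place of -0.01. There 2070 genes were higher and 5707 lower, so that 26.6% of the calls were higher in place of 51.1%.

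Clca4b (chromosome 3, 144910921 to 144932529) had a log2 fold change of 11.62 ± 1.19 (adjusted p = 3.01e-06), with 2128 ± 2546 CPM in knockout vehicle (n = 10) and 0.672 ± 0.273 CPM in wild type (n = 8). Reg3g rose by 9.76 ± 1.81 on the log2 scale (adjusted p = 0.000463) and Reg3b by 9.35 ± 1.92 (adjusted p = 0.00102). Without vehicle library 2 these rises were 8.17 and 7.82, and without wild-type library 5 that of Reg3b was 12.39. The adjusted p of Reg3b was 0.0634 with limma voom and lay between 9.33e-05 and 0.0634 over 11 other settings. Apol10a, of the apolipoprotein L family, and Gml, a gene for a membrane-anchored protein, had 0 counts in wild type and were at least 530.0-fold and at least 285.0-fold higher in the knockout, against a floor of 3 counts over the group. Clca4b, Reg3g, Reg3b and Apol10a lay above the wild-type mean in 10 of 10 knockout libraries and Gml in 9 of 10. In the other direction, Galnt17 fell by 3.08 on the log2 scale (SE 0.63, adjusted p = 0.000854), in 10 of 10 libraries. Methig1 (-3.31 ± 0.75, adjusted p = 0.00169) and Mettl7a2 (-2.73 ± 0.72, adjusted p = 0.00502), a pair of methyltransferase-like genes that overlap in the annotation and could share reads, were lower in 10 of 10 libraries. Without vehicle library 3, Galnt17 was at -4.25 and Methig1 at -4.24. Alb, the gene for albumin, was also called (-4.37 ± 1.17, adjusted p = 0.00573). Its wild-type mean of 36.4 CPM rested on wild-type library 5, with 278 CPM, and without that library the log2 fold change was -0.10 (adjusted p = 0.865).

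The interferon gamma list (targets and regulators of the interleukin 12 and interferon gamma axis) rose by 2.48 on the log2(CPM + 1) score (95% interval 1.92 to 2.97, exact permutation test, adjusted p = 0.000398). Of its tested members 17 of 18 were called higher, and 17 when adjusted over the list alone. All 10 knockout libraries scored above every wild-type library. Iigp1 and Igtp, which encode interferon-inducible GTPases that act against intracellular microbes, rose from 2.08 to 168 ± 126 CPM (adjusted p = 2.31e-06) and from 9.35 to 213 ± 134 CPM (adjusted p = 3.21e-06). The list of epithelial responses to interleukins 22 and 17 rose by 2.47 (1.82 to 3.08, adjusted p = 0.000442) in 10 of 10 libraries, with 12 of 14 members called. Its members Duox2, a producer of hydrogen peroxide at the mucosal surface, and Duoxa2, its maturation factor, rose by 2.95 ± 0.31 (adjusted p = 3.45e-06) and 4.15 ± 0.44 (adjusted p = 3.38e-06) on the log2 scale. Inflammatory cytokine genes rose by 1.2 (0.82 to 1.74, adjusted p = 0.000442), with 6 of 7 members called. Among them were Tnf (3.78 ± 0.50, adjusted p = 2.49e-05, 10 of 10 libraries) and Lif (2.16 ± 0.34, adjusted p = 0.000102, 9 of 10 libraries). For the cytokine and epithelial lists, as many members passed when adjusted over the list alone.

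Markers of several immune cell types rose. Neutrophil markers rose by 1.69 (1.04 to 2.48, adjusted p = 0.000723), with all 7 tested members called. Of these, Ly6g rose by 1.80 ± 0.24 (adjusted p = 2.49e-05), and S100a9, a subunit of calprotectin, by 8.53 ± 1.66 (adjusted p = 0.000631), or by 5.95 without vehicle library 2. T cell markers rose by 1.2 (0.91 to 1.5, adjusted p = 0.000221), with 11 of 12 called, including the T cell receptor subunits Cd3g (2.30 ± 0.33, adjusted p = 4.88e-05) and Cd3e (1.81 ± 0.26, adjusted p = 5.02e-05). Plasma cell markers rose by 1.31 (0.94 to 1.70, adjusted p = 0.000442), with 8 of 10 called. Among these, Jchain, which joins secreted immunoglobulins, rose from 203 ± 44.1 to 1011 ± 592 CPM (adjusted p = 3.28e-05) and Mzb1 by 2.01 ± 0.29 (adjusted p = 5.65e-05). Macrophage markers rose by 0.92 (0.65 to 1.22, adjusted p = 0.000398), with 13 of 14 called, and regulatory T cell markers by 0.75 (0.46 to 1.07, adjusted p = 0.00117), with 5 of 6 called. The mast cell and eosinophil list rose by 0.80 (0.54 to 1.07, adjusted p = 0.000464). Its mast cell proteases Mcpt1, Mcpt2 and Cpa3 were higher while Kit, the stem cell factor receptor that interstitial pacemaker cells also carry, was lower. In each of these lists but the regulatory T cell list (9 of 10), all 10 knockout libraries lay beyond every wild-type library. Adjusted over the list alone, the mast cell list had 4 higher members and 1 lower, and the other lists here had as many called members as over all genes. B cell and follicle markers rose by 0.96 (0.23 to 1.71, adjusted p = 0.0376), with 6 of 9 called and 7 when adjusted over the list alone, but only 5 of 10 knockout libraries lay above every wild-type library. The adjusted p of the B cell list lay between 0.023 and 0.122 over 4 other settings and passed in 2 of them.

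In the epithelium, goblet cell markers rose by 0.94 (0.69 to 1.21, adjusted p = 0.000221) in 10 of 10 libraries. The mucin gene Muc2 and the mucus protein gene Zg16 were among the 7 of 9 members called, all higher, also when adjusted over the list alone, but a score by the median over members moved the other way (-0.26, adjusted p = 0.0775). Proliferation genes rose by 0.74 (0.44 to 1.05, adjusted p = 0.00118), with 9 of 10 members called and 8 of 10 libraries above every wild-type library. Intestinal stem cell markers fell by 0.38 (-0.65 to -0.13, adjusted p = 0.0376), with Lgr5, Smoc2 and Lrig1 lower and Ephb2 higher. In 6 of 10 libraries the stem cell score lay below every wild-type library. The stem cell difference was -0.06 (adjusted p = 0.75) by the median over members, and its adjusted p lay between 0.0152 and 0.75 over 4 other settings. Drug and xenobiotic metabolism fell by 0.57 (-0.87 to -0.31, adjusted p = 0.00177) in 10 of 10 libraries, with 6 members lower, such as the cytochromes Cyp3a13 and Cyp2c55, and the exporter gene Abcc3 higher. Adjusted over the list alone, 7 members were lower. Enteroendocrine markers rose by 0.23 (0.05 to 0.41, adjusted p = 0.0419), with Gcg and Cck, the genes for proglucagon and cholecystokinin, called and 6 of 10 libraries above every wild-type library. Its adjusted p lay between 0.00418 and 0.337 over 4 other settings, 2 of which did not pass. Colonocyte transport genes did not pass as a list (0.20, adjusted p = 0.0964). The list held 6 higher members such as Aqp8 and Car4 and 3 lower members, Car1, Car2 and Scnn1b, and its median member was at -0.24, opposite in sign to the mean. Adjusted over the list alone, 6 were higher and 5 lower. Tuft cell markers (0.22, adjusted p = 0.176) and squamous epithelium markers (-0.19, adjusted p = 0.241) did not pass either. Of these, Sh2d6 among tuft cell markers and Krt13 among squamous markers were higher and the squamous keratin gene Krt14 was lower. When adjusted over the list alone, Sh2d6 did not pass, and 1 squamous member was higher and 2 were lower. The squamous list passed by the median over members (adjusted p = 0.0306), with an adjusted p of up to 0.25 in the other 3 settings.

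Smooth muscle markers fell by 1.81 (-2.72 to -0.95, adjusted p = 0.00442), with all 8 members called lower. Tagln, an actin-binding protein of contractile cells, was at 543 ± 402 CPM against 1312 ± 350 CPM in wild type (adjusted p = 0.0143, lower in 10 of 10 libraries). Acta2, smooth muscle actin, was at 498 ± 411 against 1285 ± 404 CPM (adjusted p = 0.0158, 9 of 10 libraries). Enteric neuron and glia markers fell by 1.11 (-1.57 to -0.62, adjusted p = 0.00339), with 8 of 11 called lower. These included the glial regulator Sox10 (-1.87 ± 0.54, adjusted p = 0.00878) and Uchl1 of enteric neurons (-1.15 ± 0.35, adjusted p = 0.0126), each lower in 9 of 10 libraries, and Sox10 was at -2.56 without vehicle library 3. Fibroblast and matrix genes fell by 0.69 (-0.94 to -0.39, adjusted p = 0.00182), with 11 of 14 lower and Tgfb1 higher. For each of these lists, 8 of 10 knockout libraries lay below every wild-type library, and adjusting over the list alone gave as many called members. Matrix metalloproteinases rose by 0.75 (0.34 to 1.3, adjusted p = 0.00485) in 9 of 10 libraries, with Mmp3, Mmp10, Mmp12 and Mmp13 higher and Mmp2, a product of fibroblasts, lower. Genes of hypoxia and angiogenesis rose by 0.71 (0.49 to 0.98, adjusted p = 0.000442), with 8 of 12 called and 10 when adjusted over the list alone. The list of genes for adhesion of leukocytes to endothelium and for the endothelial response to acidosis rose by 0.71 (0.53 to 0.95, adjusted p = 0.000221). Of its 12 tested members 10 were higher, including the adhesion molecules Selp, Icam1, Vcam1 and Madcam1, and adjusting over the list alone added 1 lower member. All 10 knockout libraries exceeded every wild-type library in both lists. General endothelial markers did not pass (-0.21, adjusted p = 0.111), although Tek, Tie1, Esam and Cldn5 were lower. None of them passed in edgeR when adjusted over the list alone. Their adjusted p lay between 0.0313 and 0.112 over 4 other settings and passed in 2. Adipocyte (-0.61, adjusted p = 0.39) and erythroid markers (0.42, adjusted p = 0.39) had no called member. In total, 18 of 29 lists rose, 5 fell and 6 did not pass, and 23 had an unadjusted p under 0.05. The smallest unadjusted p was 2.29e-05, the smallest these permutations can give.

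Compound 13 is directed at GPR4, so proton-sensing receptor genes were followed in each comparison. Gpr4 itself (chromosome 7, 19212538 to 19224174), which is mainly expressed by endothelium, was at 1.32 ± 0.507 CPM in knockout vehicle and 1.10 ± 0.258 CPM in wild type. The log2 fold change of 0.26 ± 0.25 did not pass (adjusted p = 0.406, higher in 6 of 10 libraries). Relatives of it on immune cells rose in 10 of 10 libraries. Gpr65 (chromosome 12, 98268635 to 98276644) rose by 1.2 ± 0.26 (adjusted p = 0.00138) and Gpr132 (chromosome 12, 112850873 to 112868228) by 1.44 ± 0.32 (adjusted p = 0.00158). The list of proton-sensing receptors rose by 0.66 (0.43 to 0.88, exact permutation test, adjusted p = 0.000939) in 8 of 10 libraries. Il12a, which encodes the p35 subunit of interleukin 12, did not pass (0.36 ± 0.35, adjusted p = 0.413). Il12b, the gene for p40, fell below the expression filter of this fit, at 0.525 ± 0.361 CPM in the knockout and 0.0333 ± 0.0475 CPM in wild type, as did Il23a, at 0.254 ± 0.180 and 0.316 ± 0.160 CPM. The list of the interleukin 23 and 17 axis, of which only 4 of 12 members were expressed enough to be tested, rose by 0.38 (0.10 to 0.65, adjusted p = 0.0387). The receptor gene Il12rb1 was higher, and 6 of 10 libraries lay above every wild-type library. Its adjusted p lay between 0.035 and 0.296 over 4 other settings, 3 of which did not pass.

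**Figure D1:**
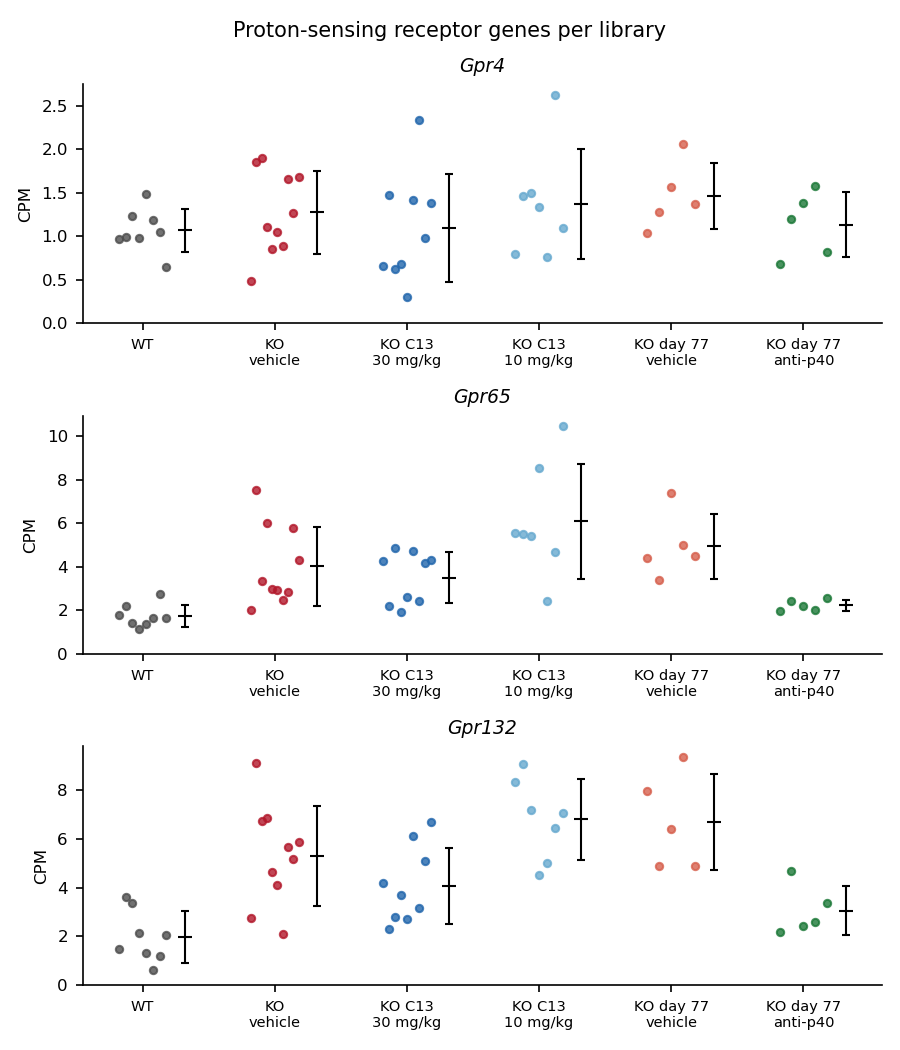
Expression of the proton-sensing receptor genes Gpr4, Gpr65 and Gpr132 in each library (points, CPM scaled by TMM over all libraries) of the 6 groups, with mean ± SD as bars. Mean Gpr4 lay between 1.07 CPM in wild type and 1.46 CPM in day 77 vehicle, whereas mean Gpr65 was 1.75 CPM in wild type, 4.03 CPM in knockout vehicle, 4.95 CPM in day 77 vehicle and 2.24 CPM with anti-p40.

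Whether the GPR4 antagonist changed the knockout colon was asked first at 30 mg/kg. No gene passed between 9 treated and 10 vehicle libraries, and none of the gene lists differed. The endothelial adhesion list had a lower score at 30 mg/kg (-0.32, 95% interval -0.64 to -0.03). This did not pass the exact permutation test (unadjusted p = 0.0571, adjusted p = 0.624). Proton-sensing receptors (-0.18, -0.45 to 0.09, adjusted p = 0.634), the interferon gamma list (-0.19, -0.75 to 0.39, adjusted p = 0.785) and the epithelial response to interleukins 22 and 17 (-0.26, -1.03 to 0.48, adjusted p = 0.785) had intervals that included 0. B cell and follicle markers were lower (-0.67, -1.28 to -0.04) without passing (adjusted p = 0.624), although 8 of their 9 members were called lower when adjusted over the list alone, against 0 over all genes. The endothelial adhesion list had 3 of 13 members lower when adjusted over the list alone and 0 over all genes.

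In edgeR, 0 of 16948 genes passed between 30 mg/kg and vehicle, 1004 had an unadjusted p under 0.05 and the smallest adjusted p was 0.61. Voom called 0 genes and DESeq2 3, Inhbb among them. Inhbb, a subunit of activin B and inhibin B, was at 0.888 ± 0.426 CPM against 2.34 ± 1.19 CPM and was lower in 9 of 9 libraries. Its log2 fold change was -1.39 ± 0.30 (adjusted p = 0.61 in edgeR, between 0.0165 and 0.999 over 13 other settings). The other calls of DESeq2, named here after their values were seen, were the predicted gene Gm45837 (adjusted p = 1.27e-08) and the long noncoding RNA Gm26883 (adjusted p = 0.000152), both without any count at 30 mg/kg and in most vehicle libraries. Phf13, a chromatin reader, was at 22.8 ± 5.15 against 15.7 ± 1.2 CPM (0.54 ± 0.12, adjusted p = 0.61, above the vehicle mean in 8 of 9 libraries). Arrdc4 (0.50 ± 0.11), Sertad3 (0.46 ± 0.11) and Mat2a (0.34 ± 0.08) followed with an adjusted p of 0.723 each, above the vehicle mean in 8, 9 and 9 of 9 libraries. Gpr4 was at 1.05 ± 0.600 CPM against 1.21 ± 0.456 CPM (-0.21 ± 0.33, adjusted p = 0.999). Gpr65 (-0.20 ± 0.27), Gpr132 (-0.37 ± 0.24), Il12a (-0.51 ± 0.58) and Il12b (-1.05 ± 0.55) had adjusted p-values from 0.859 to 0.999. Il23a fell below the expression filter of this fit, at 0.271 ± 0.160 CPM against 0.233 ± 0.163 CPM. The authors' deposited table listed 0 genes as higher and 1 as lower, Gm45837 (adjusted p = 1.57e-12).

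At 10 mg/kg, the transcripts that passed against vehicle were an rRNA transcript, CT010467.1, and a processed pseudogene, Gm9625, and no protein-coding gene passed. CT010467.1 (chromosome 17, 39846353 to 39848827) rose from 925 ± 305 CPM (n = 10) to 2595 ± 883 CPM (n = 7), a log2 fold change of 1.49 ± 0.21 (adjusted p = 0.00198, higher in 7 of 7 libraries). Gm9625 (chromosome 13, 67810246 to 67811200) fell from 48.8 ± 4.03 to 32.5 ± 4.78 CPM (-0.58 ± 0.10, adjusted p = 0.0233, lower in 7 of 7 libraries). Both are copies of sequences found elsewhere in the genome, and their counts are uncertain. The share of all counts held by CT010467.1 and Gm10925, a pseudogene that resembles mitochondrial DNA, was 0.721 ± 0.16% at 10 mg/kg and 0.345 ± 0.066% in vehicle, the lowest of the first-cohort groups, with 0.475 ± 0.124% at 30 mg/kg and 0.403 ± 0.117% in wild type.

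None of the 29 lists passed at 10 mg/kg, and none had an unadjusted p under 0.05. Proton-sensing receptors had a higher score (0.27, 95% interval 0.01 to 0.51, exact permutation p = 0.0882, adjusted p = 0.643). The interferon gamma list (0.52, -0.13 to 1.17, adjusted p = 0.643) and the epithelial response to interleukins 22 and 17 (0.40, -0.45 to 1.28, adjusted p = 0.757) did not pass. Neither did the B cell list (0.41, -0.08 to 0.94, adjusted p = 0.643) or the endothelial adhesion list (0.15, -0.24 to 0.48, adjusted p = 0.757). These lists had 0 called members each, also when adjusted over the list alone in edgeR. Gpr4 (0.11 ± 0.35, adjusted p = 0.919) and Gpr65 (0.60 ± 0.28, adjusted p = 0.432, above the vehicle mean in 6 of 7 libraries) did not pass. The same held for Gpr132 (0.37 ± 0.25, adjusted p = 0.599), Il12a (0.93 ± 0.60, adjusted p = 0.58) and Il12b (0.24 ± 0.56, adjusted p = 0.887). The genes next in order of p were Taf15 (-0.63 ± 0.13), Gm10925 (1.01 ± 0.20) and Rnaseh2c (-0.66 ± 0.14), each with an adjusted p of 0.107.

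With 2 of 16948 genes, the count at 10 mg/kg moved with the tool, as 1865 genes had an unadjusted p under 0.05, voom called 1 and DESeq2 72. The authors' deposited table listed 36 higher and 46 lower genes, CT010467.1 and Gm9625 among them. Leaving out vehicle library 2, 5, 7, 8 or 10 or 10 mg/kg library 1, 5 or 7 left only CT010467.1, with an adjusted p of 0.0515 to 0.0965 for Gm9625. Leaving out 10 mg/kg library 2, 4 or 6 gave 8, 4 or 18 genes, and no gene passed without the libraries that carried pancreatic RNA (0 in edgeR, with 852 at an unadjusted p under 0.05).

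The doses were also compared with each other, as the same compound at different dose. No gene or list passed. The list with the smallest p was that of B cell and follicle markers, with a score difference of -1.08 (95% interval -1.58 to -0.61, exact permutation p = 0.0021, adjusted p = 0.0608). Of the 30 mg/kg libraries, 7 of 9 lay below every 10 mg/kg library. Their 9 tested members were all called lower when adjusted over the list alone, against 0 over all genes. Other lists with an unadjusted p under 0.05 and lower scores at 30 mg/kg were the interleukin 23 and 17 axis (-0.36, adjusted p = 0.0693), proton-sensing receptors (-0.44, -0.67 to -0.20, adjusted p = 0.0693) and plasma cells (-0.64, adjusted p = 0.0945). Further such lists were the endothelial adhesion list (-0.47, -0.78 to -0.13, adjusted p = 0.0945), the interferon gamma list (-0.71, -1.21 to -0.18, adjusted p = 0.0945), T cells (-0.52, adjusted p = 0.0947) and macrophages (-0.51, adjusted p = 0.103). Adjusted over the list alone, 3 plasma cell markers, 4 endothelial adhesion genes, 3 interferon gamma genes and 5 macrophage markers were lower, and 0 genes of the interleukin 23 and 17 axis and of the T cell list passed in edgeR. Adipocyte markers (1.66, adjusted p = 0.0945, with 5 of 5 members higher when adjusted over the list alone) and smooth muscle markers (1.38, adjusted p = 0.131) had higher scores. Enteric neuron and glia markers (0.63, adjusted p = 0.219) and the epithelial response to interleukins 22 and 17 (-0.66, adjusted p = 0.22) had an unadjusted p above 0.05. By the median over members, the B cell list (-1.09) and the plasma cell list (-1.25) passed with an adjusted p of 0.0342 each, and over 5 other settings their adjusted p reached 0.365 and 0.558.

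Inhbb was the gene with the smallest p between doses, at 0.888 ± 0.426 CPM at 30 mg/kg and 2.97 ± 0.922 CPM at 10 mg/kg (-1.73 ± 0.32, lower in 9 of 9 libraries). It was followed by Tmco6 (0.52 ± 0.10), Gm9625 (0.52 ± 0.10), Pkd2l2 (1.25 ± 0.25) and Pfdn1 (0.56 ± 0.11), each higher in 9 of 9 libraries, and all had an adjusted p of 0.0747. Gpr4 (-0.32 ± 0.36, adjusted p = 0.706) did not pass. The same was true of Gpr65 (-0.80 ± 0.29, adjusted p = 0.208), Gpr132 (-0.74 ± 0.26, adjusted p = 0.194), Il12a (-1.44 ± 0.63, adjusted p = 0.292) and Il12b (-1.29 ± 0.59, adjusted p = 0.315). Each of these lay below the 10 mg/kg mean in 9 of 9 libraries. In edgeR 0 of 16948 genes passed and 2450 had an unadjusted p under 0.05, while DESeq2 called 343 genes and voom 1, Inhbb. Leaving out 30 mg/kg library 3, 6 or 9 gave 1, 22 or 75 genes and leaving out 10 mg/kg library 2, 5 or 6 gave 3, 28 or 1.

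Anti-p40 was compared with vehicle in the knockout cohort labelled day 77, to ask what blocking interleukins 12 and 23 did to the colon. The epithelial response genes of interleukins 22 and 17, interferon gamma targets and markers of neutrophils, T cells and macrophages fell, and smooth muscle, xenobiotic metabolism, colonocyte and enteric nerve genes rose. Clca4b, among the genes with the largest rises in the knockout, fell from 2604 ± 1636 to 10.2 ± 9.21 CPM (n = 5 each, log2 fold change -7.99 ± 0.78, adjusted p = 0.000272). The neutrophil genes S100a8 (-8.40 ± 1.23, adjusted p = 0.00231) and S100a9 (-7.76 ± 1.54, adjusted p = 0.00934) fell in 5 of 5 libraries. So did Ltf, the gene for lactoferrin (-6.76 ± 0.64, adjusted p = 0.000236), and Reg3b (-7.83 ± 1.73, adjusted p = 0.0148). Without day 77 vehicle library 3, S100a8 was at -7.01, S100a9 at -5.22 and Reg3b at -5.19, and without anti-p40 library 5 Reg3b was at -10.08. Clca4b ranged from -8.68 to -7.57 with 1 library left out. The adjusted p of Reg3b lay between 0.00687 and 0.0517 over 9 other settings and passed in 8 of them. In edgeR 1375 genes were higher and 1370 lower with anti-p40, or 2745 of 16470, with 584 and 589 changed at least 2-fold. Leaving out anti-p40 library 2 gave 1637 genes, and no other single library moved the count by more than 1.5 times.

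The epithelial response list fell by 2.38 (95% interval -3.08 to -1.84, exact permutation test, adjusted p = 0.0192), with 14 of 15 members called lower. Muc1, a membrane mucin, fell from 38.8 ± 7.16 to 7.24 ± 1.3 CPM (adjusted p = 4.54e-05), and Nos2, the inducible nitric oxide synthase, from 570 ± 371 to 15.2 ± 16.5 CPM (adjusted p = 0.00124). The interferon gamma list fell by 1.65 (-2.27 to -1.02), with 17 of 19 called and 18 when adjusted over the list alone. Its member Ido1, a tryptophan-degrading enzyme, fell by 4.68 on the log2 scale (SE 0.70, adjusted p = 0.00222). Without anti-p40 library 5 the log2 fold change was -5.61 for Ido1 and -6.16 for Nos2. Neutrophil markers fell by 1.77 (-2.72 to -1.10), with 5 of 9 called and 7 when adjusted over the list alone. T cell markers fell by 1.07 (-1.41 to -0.73), with 9 of 12 called and 10 over the list alone, among them Cd3g (-2.18 ± 0.33, adjusted p = 0.00219) and Cd3e (-1.84 ± 0.31, adjusted p = 0.00386). Macrophage markers fell by 1.04 (-1.3 to -0.80), with 12 of 14 called, also over the list alone. Ly6c2, a marker of inflammatory monocytes, fell from 40.7 to 8.58 CPM (adjusted p = 0.000272) and Cd14, a receptor for bacterial lipopolysaccharide, from 231 to 55.3 CPM (adjusted p = 0.000677). Inflammatory cytokines fell by 0.92 (-1.48 to -0.51), with 2 of 7 called, Tnf (-3.06 ± 0.45, adjusted p = 0.00184) and Lif (-2.0 ± 0.38, adjusted p = 0.00695), and 3 over the list alone. Regulatory T cell markers fell by 0.68 (-0.85 to -0.50), with 3 of 6 called, Foxp3 included, and 5 over the list alone. All 5 anti-p40 libraries lay below every vehicle library for each of these lists, each list had an adjusted p of 0.0192, and the unadjusted p of 0.00794 was the smallest that 5 against 5 can give.

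In the other direction, smooth muscle markers rose by 1.13 (95% interval 0.57 to 1.73, exact permutation test), with 6 of 8 called and 8 when adjusted over the list alone. They included Cnn1, the contractile protein calponin (1.22 ± 0.21, adjusted p = 0.00396), and Tagln (1.22 ± 0.26, adjusted p = 0.0112). Drug and xenobiotic metabolism rose by 1.08 (0.77 to 1.47), with 5 members higher and the exporter gene Abcc3 lower, and with 6 higher and 1 lower when adjusted over the list alone. The cytochrome genes Cyp2c65 and Cyp3a13 rose from 0.465 to 3.13 CPM (adjusted p = 0.000302) and from 15.6 to 39.4 CPM (adjusted p = 0.000425). Colonocyte genes rose by 0.69 (0.48 to 0.92), with 5 higher, such as the anion exchanger gene Slc26a3 and Car1, and 3 lower, the proton pump gene Atp12a, the keratin gene Krt20 and the bile acid exporter gene Slc51b. Adjusted over the list alone, 7 were higher and 3 lower. Enteric neuron and glia markers rose by 0.68 (0.38 to 1.06), with 6 higher and Tac1, the gene for substance P, lower, and 9 higher and 1 lower over the list alone. These lists had an adjusted p of 0.0192 with all 5 anti-p40 libraries above every vehicle library. Without anti-p40 library 2 the smooth muscle and the neuron lists no longer passed (adjusted p = 0.0658 and 0.0628).

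Weaker differences were seen in further lists. Endothelial adhesion genes fell by 0.53 (95% interval -0.84 to -0.23, exact permutation test, adjusted p = 0.046), with 5 of 13 called and 7 when adjusted over the list alone. Mast cell and eosinophil markers fell by 0.45 (-0.72 to -0.17, adjusted p = 0.046), with 3 of 8 called, Mcpt1, Mcpt2 and Prg2. Goblet cell markers rose by 0.63 (0.23 to 1.08, adjusted p = 0.046), with 1 of 9 called, Clca1, and 4 over the list alone. For each of these lists, 3 of 5 anti-p40 libraries lay beyond every vehicle library. The endothelial adhesion list lost its call without any 1 library other than vehicle library 5 (adjusted p up to 0.0921). The mast cell list lost it without vehicle library 1, 2 or 5 or any anti-p40 library (up to 0.102), and the goblet cell list without any 1 library other than anti-p40 library 4 (up to 0.0948). Over 4 other settings, the adjusted p lay between 0.046 and 0.876 for endothelial adhesion (1 passed, and 0.876 was by the median over members). It lay between 0.0354 and 0.0812 for mast cells (2 passed) and between 0.0209 and 0.0812 for goblet cells (3 passed). The interleukin 23 and 17 axis (-0.35, adjusted p = 0.153) and general endothelial markers (0.29, adjusted p = 0.0767) did not pass, but did so without vehicle library 3 (adjusted p = 0.046) and without vehicle library 4 (adjusted p = 0.0329), respectively. In all, 5 lists rose, 10 fell and 14 did not pass, and 18 had an unadjusted p under 0.05.

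Proton-sensing receptors that had risen in the knockout fell with anti-p40. As a list they fell by 0.64 (95% interval -0.87 to -0.41, exact permutation test, adjusted p = 0.0192), with all 5 libraries below every vehicle library. Gpr65 fell from 5.20 ± 1.6 to 2.37 ± 0.276 CPM (-1.13 ± 0.22, adjusted p = 0.00691) and Gpr132 from 7.03 ± 2.09 to 3.23 ± 1.09 CPM (-1.12 ± 0.27, adjusted p = 0.0169). The call of Gpr132 was lost in 1 of 10 other settings, limma on TPM without a filter (adjusted p = 0.0829, and 0.000422 at the lowest). Gpr4 was at 1.2 ± 0.396 CPM against 1.54 ± 0.409 CPM (-0.35 ± 0.28, adjusted p = 0.424, below the vehicle mean in 4 of 5 libraries). Il12a did not pass (-0.05 ± 0.49, adjusted p = 0.956), and Il12b (0.247 ± 0.161 against 0.733 ± 0.459 CPM) and Il23a (0.462 ± 0.106 against 0.313 ± 0.0468 CPM) fell below the expression filter of this fit.

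Among the genes with the largest rises with anti-p40, Rnase2a, an eosinophil-type ribonuclease, rose from 0.0516 to 3.99 CPM (6.16 ± 0.65, adjusted p = 0.000369). Ang4, an antimicrobial angiogenin, rose by 6.08 ± 1.39 (adjusted p = 0.0166) and Mptx1, a mucosal pentraxin, by 5.84 ± 1.42 (adjusted p = 0.0204), in 5 of 5 libraries each. Mptx1 lost its call without vehicle library 2, 3 or 4 (adjusted p = 0.0505 to 0.0749). Without anti-p40 library 5 Ang4 was at 4.77 and Mptx1 at 3.68, and without vehicle library 5 Ang4 was at 7.46. Over 10 other settings the adjusted p reached 0.0618 for Ang4 (9 passed) and 0.0689 for Mptx1 (8 passed). Pnliprp1 (7.97 ± 2.46, adjusted p = 0.0498) and Clps (5.56 ± 1.54, adjusted p = 0.0336), which encode a lipase-related protein and colipase of the pancreas, were also called. However, anti-p40 library 5 carried pancreatic RNA, and without it the log2 fold changes were 0.88 (adjusted p = 0.407) and 1.85 (adjusted p = 0.0193), so that only the call of Pnliprp1 was lost. The calls of both were lost without any 1 vehicle library, and that of Pnliprp1 also without anti-p40 library 2, with adjusted p-values of 0.0543 to 0.141.

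**Figure D2:**
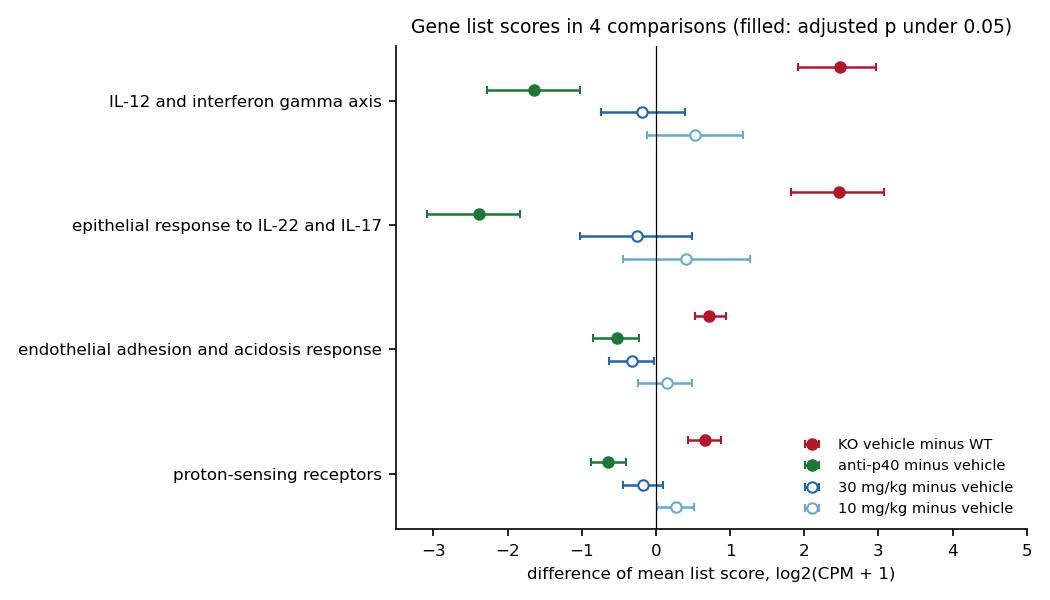
Difference of the mean list score, on the log2(CPM + 1) scale, for 4 gene lists in 4 comparisons (colours), with 95% bootstrap intervals as bars and filled points for an adjusted p under 0.05. The interferon gamma list differed by 2.48 between knockout vehicle and wild type, by -1.65 with anti-p40, by -0.19 at 30 mg/kg and by 0.52 at 10 mg/kg.

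Acinar genes of the pancreas were seen in 10 libraries at 500 CPM or more. By group these were 1 of 8 wild-type, 4 of 10 knockout vehicle, 3 of 9 30 mg/kg, 0 of 7 10 mg/kg, 0 of 5 day 77 vehicle and 1 of 5 anti-p40 libraries and the unassigned library. Without these libraries 7674 genes were called between knockout and wild type and 2494 with anti-p40, of which 2252 were among the 2745 called with all libraries. The list of 14 acinar genes was chosen after they were seen, and 5 were expressed enough to be scored in the knockout comparison and 3 (Clps, Ctrl and Pnliprp1) with anti-p40. The score did not pass between knockout vehicle and wild type (1.82, exact permutation p = 0.27) and was higher with anti-p40 (1.94, 95% interval 0.36 to 4.80, exact permutation p = 0.0159, not adjusted). Most of this difference rested on anti-p40 library 5, and without it the difference was 0.543 (exact permutation p = 0.0238).

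**Figure D3:**
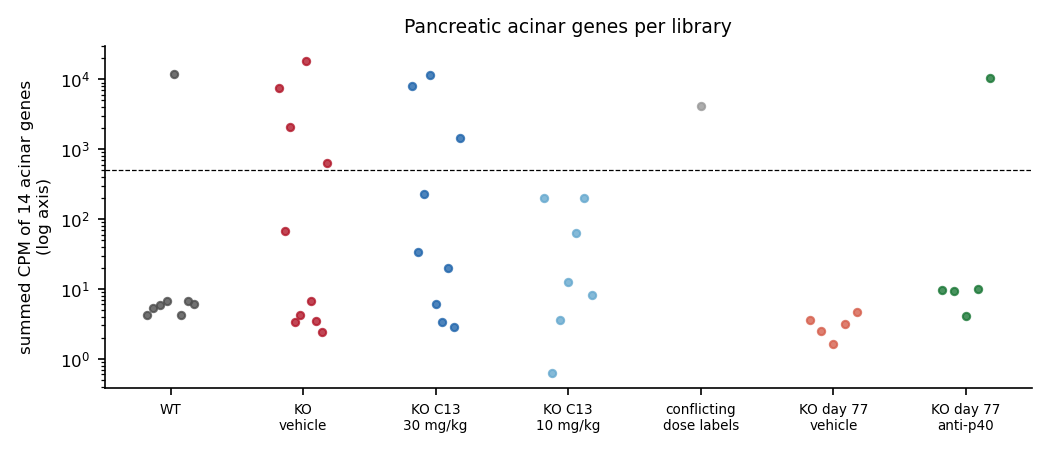
Summed CPM of 14 pancreatic acinar genes in each library by group, on a log axis, with the dashed line at 500 CPM. Values reached 18300 CPM in knockout vehicle, 11840 CPM in wild type, 11730 CPM at 30 mg/kg and 10480 CPM with anti-p40, and stayed at or below 201 CPM at 10 mg/kg and 4.66 CPM in day 77 vehicle.

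The cohorts were then compared by scores. The disease score, made of 1169 genes higher and 934 genes lower in knockout vehicle than in wild type, was -0.002 ± 0.366 with anti-p40 and 1.557 ± 0.503 in day 77 vehicle. It fell by 1.56 (95% interval -2.07 to -1.10, exact permutation p = 0.00794, the smallest possible). For compound 13, the disease score differed from held-out vehicle libraries by a median of -0.09 (range -0.78 to 0.22 over 20 splits of the vehicle libraries, median exact permutation p = 0.596) at 30 mg/kg and of 0.67 (-0.13 to 0.97, median p = 0.235) at 10 mg/kg. Wild type differed from held-out vehicle by a median of -2.07 (-3.20 to -1.52, median exact permutation p = 0.000777). The same 8 wild-type libraries had also served to choose the signature genes. Part of this difference is therefore built in, and it serves only as a measure of scale. The anti-p40 score, from 1372 genes higher and 1363 lower with anti-p40, was -0.965 ± 0.502 at 30 mg/kg, -1.511 ± 0.616 at 10 mg/kg, -1.156 ± 0.698 in vehicle and 0.436 ± 0.106 in wild type. It did not differ from vehicle by the exact permutation test at 30 mg/kg (0.19, -0.32 to 0.71, p = 0.508) or 10 mg/kg (-0.36, -0.95 to 0.24, p = 0.295), whereas wild type was higher than vehicle by 1.59 (1.17 to 2.01, p = 0.000137).

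**Figure D4:**
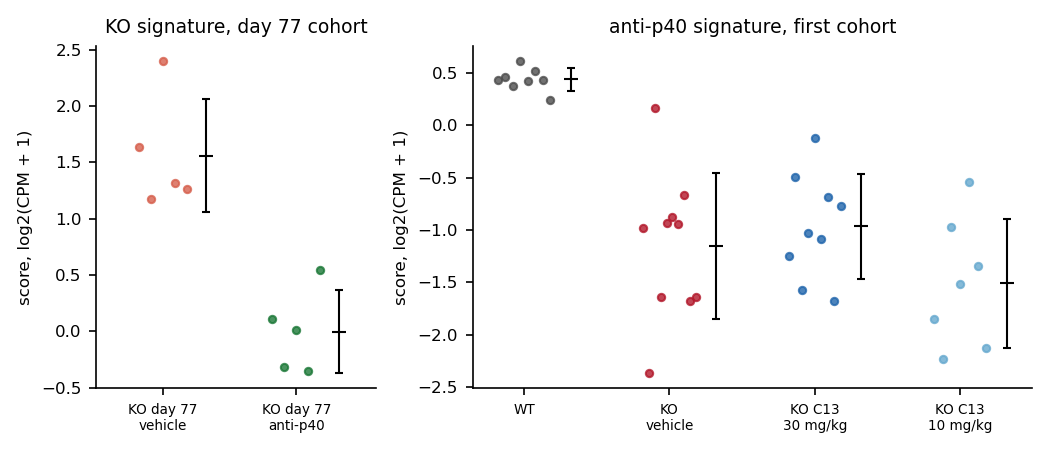
Disease score per library in the day 77 groups (left) and anti-p40 score per library in the groups of the first cohort (right), as mean log2(CPM + 1) of the higher minus the lower genes of each signature, with mean ± SD as bars. The anti-p40 libraries lay between -0.36 and 0.55 and the day 77 vehicle libraries between 1.17 and 2.40, and the anti-p40 score of vehicle libraries (-2.36 to 0.16) overlapped with that at 30 mg/kg (-1.68 to -0.13) and 10 mg/kg (-2.23 to -0.54).

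Across 16111 genes, the knockout effect and the anti-p40 effect had a Pearson correlation of -0.779 (Spearman -0.753, permutation p = 0.0794 over regroupings of the libraries). Genes are not independent replicates in such correlations. Of the genes called in both comparisons, 1201 were higher in the knockout and lower with anti-p40, against 341.6 if the lists were independent. In turn, 961 were lower in the knockout and higher with anti-p40, against 332.8, and 17 and 3 were higher in both or lower in both, against 349.7 and 325.0. The anti-p40 effect had a correlation of 0.299 with the 30 mg/kg effect (Spearman 0.268, permutation p = 0.588, 16254 genes) and of -0.412 with the 10 mg/kg effect (Spearman -0.359, permutation p = 0.439). The effects of both doses, which share their vehicle libraries, had a correlation of -0.0154 (Spearman 0.0899) where unchanged groups against the same vehicle gave 0.443 (0.417 to 0.481 in 20 simulations). The covariance was -0.000741 against a simulated 0.0193. Each gene was simulated independently of the others, unlike genes in real libraries. The narrow simulated range therefore cannot show that the dose effects differ from those of unchanged groups. With the vehicle libraries split between the doses, the median correlation was -0.321 (-0.621 to 0.191 over the splits) and the median covariance -0.0216.

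The effects of anti-p40 and of 30 mg/kg were finally tested against each other, each relative to its own vehicle. The cohorts may differ in age, time and batch, which cannot be told apart from the treatments here. Genes that differed included the gasdermin genes Gsdmc4, Gsdmc2 and Gsdmc3 and the cytochrome gene Cyp2c55, which had higher log2 fold changes with anti-p40, and Clca4b, Plet1, Ces2f, Ltf and Tnfrsf8, which had lower ones. In edgeR 80 genes had a higher and 217 a lower effect of anti-p40, or 297 of 18021. Clca4b differed by -7.49 ± 1.47 on the log2 scale (adjusted p = 0.00336) and Plet1, a surface protein of epithelial progenitors, by -6.17 ± 1.22 (adjusted p = 0.00341). Ces2f, a carboxylesterase, differed by -5.71 ± 1.12 (adjusted p = 0.00341), Ltf by -5.99 ± 1.39 (adjusted p = 0.0146) and Tnfrsf8, the lymphocyte receptor CD30, by -5.06 ± 1.02 (adjusted p = 0.00393). Gsdmc4 differed by 5.61 ± 1.16 (adjusted p = 0.0053) and Cyp2c55 by 5.32 ± 1.25 (adjusted p = 0.0155). Tdo2, an enzyme of tryptophan breakdown, differed by 4.24 ± 0.97 (adjusted p = 0.0121), Gsdmc2 by 4.01 ± 0.93 (adjusted p = 0.0141) and Gsdmc3 by 3.98 ± 1.01 (adjusted p = 0.0275). For each gene, 5 of 5 anti-p40 libraries lay beyond the day 77 vehicle mean in the direction of the difference. This count shows the anti-p40 effect alone, as no 30 mg/kg library enters it. Plet1 was at 11.5 CPM with anti-p40 and 964 CPM in day 77 vehicle. No difference between the treatments passed for Gpr4 (-0.14 ± 0.48, adjusted p = 0.915), Gpr65 (-0.93 ± 0.40, adjusted p = 0.241) or Gpr132 (-0.75 ± 0.44, adjusted p = 0.417). None passed for Il12a (0.46, adjusted p = 0.832), Il12b (-0.51, adjusted p = 0.828) or Il23a (0.36, adjusted p = 0.841). DESeq2 called 638 genes, voom 1225 and edgeR without the libraries carrying pancreatic RNA 116, of which 112 were among the 297. Leaving out vehicle library 2 or 30 mg/kg library 5 gave 577 or 507 genes and leaving out day 77 vehicle library 3 or anti-p40 library 2 gave 167 or 170. Tdo2 lost its call without anti-p40 library 2 (adjusted p = 0.0579) and Gsdmc3 without day 77 vehicle library 2 or 3 or anti-p40 library 2 or 5 (0.0534 to 0.0794). Over 8 other settings, calls were also lost without the libraries carrying pancreatic RNA for Cyp2c55 (0.118), Gsdmc2 (0.112), Gsdmc3 (0.163) and Ltf (0.0705). Gsdmc3 lost it without a filter (0.0526) and Ltf by voom (0.0711) as well. With 1 library left out, the log2 differences ranged from 4.83 to 6.32 for Cyp2c55, 4.99 to 5.89 for Gsdmc4, 3.58 to 4.87 for Tdo2, 3.51 to 4.23 for Gsdmc2 and 3.62 to 4.23 for Gsdmc3. They ranged from -7.24 to -5.81 for Plet1, -6.82 to -5.52 for Ltf, -8.17 to -7.02 for Clca4b, -6.18 to -5.48 for Ces2f and -5.38 to -4.78 for Tnfrsf8.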

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

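The tests of spill-over, of anti-p40 as the source of pancreatic RNA, of carry-over at low levels, of low-complexity libraries, of rRNA, of the muscle layer, of dose and of other splits of the libraries were chosen only after the results were seen. The tests of tissue carry-over at high levels, of the acinar score with anti-p40 and of gene length were written before their results were seen.

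Pancreatic acinar genes reached 500 CPM or more in 10 libraries, namely wild-type library 5 (11840 CPM), vehicle libraries 1 (7413), 3 (2082), 6 (18300) and 10 (626.5), 30 mg/kg libraries 1 (8069), 4 (11730) and 9 (1438), anti-p40 library 5 (10480) and the unassigned library (4160). Reads spilling over from the highest library would leave the others of the first cohort at about 1 level, but the highest of these was 18760 times the lowest above 0, and 9 of the 10 libraries had no anti-p40, so that neither spill-over nor the antibody accounts for them. The acinar genes kept their ratios between these libraries (median Pearson r = 0.899 over pairs, 0.588 to 0.991, across 14 genes), which is consistent with pancreatic tissue carried over with the colon, a hypothesis. Without anti-p40 library 5 the acinar score, which rests on 3 genes here, was still higher with anti-p40 than with vehicle (1.346 ± 0.257 against 0.803 ± 0.199, exact permutation p = 0.0238, where 0.00794 is the smallest possible for 4 against 5). Carry-over does not account for these low levels, since the other 13 acinar genes summed to at most 0.506 times Clps in anti-p40 libraries 1 to 4 and to 27.8 to 56.2 times Clps in the 10 libraries. Clps was at 2.71 to 7.62 CPM in these anti-p40 libraries and 0.46 to 3.14 CPM in day 77 vehicle, and an effect of anti-p40 stays open as a hypothesis. The acinar score is no independent support for such an effect. Its list was picked after its genes were seen, and Clps and Pnliprp1 were among the genes called in this comparison. Islet genes at 1 CPM or more were seen in 5 libraries, 3 of which were among the 10, with Ins2 at 18.6 CPM in vehicle library 6 and 18 CPM in 30 mg/kg library 4.

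Between 10 mg/kg and vehicle, the rRNA transcript CT010467.1 and the pseudogene Gm9625 were the called genes. Libraries of low complexity (10 mg/kg libraries 1, 2 and 4) do not account for CT010467.1, whose log2 fold change was 1.61 without them (adjusted p = 0.0132, 1.49 ± 0.21 with them). For Gm9625 the log2 fold change without them was -0.51 (adjusted p = 0.187, -0.58 ± 0.10 with them), and fewer libraries alone could end that call, so the explanation stays open. The fold changes of all 16920 genes with a length had a rank correlation of 0.093 with gene length, within the range of 1000 random regroupings (-0.206 to 0.184, p = 0.404), which leaves a length bias open too. If rRNA and mitochondrial RNA had been left in these libraries, the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 would be higher too. They held 0.174 ± 0.054% of counts at 10 mg/kg and 0.137 ± 0.062% in vehicle, a difference of 0.037 (exact permutation p = 0.226) that decides neither way, so that left-over RNA and an effect of the dose both stay open. All mitochondrial genes held 5.45 ± 0.67% of counts at 10 mg/kg and 4.66 ± 0.50% in vehicle, a difference that was not tested. Their share was 5.07 ± 1.02% at 30 mg/kg and 5.10 ± 0.39% in wild type.

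Scores of lymphoid lists, most of all B cells and follicles (-1.08, adjusted p = 0.0608), were lower at 30 mg/kg than at 10 mg/kg, but no list passed after adjustment on mean scores. By the median over members the B cell (-1.09) and plasma cell lists (-1.25) passed (adjusted p = 0.0342 each), so that whether there is a difference to explain depends on the score. A larger share of the muscle layer at 30 mg/kg stays open. Smooth muscle markers (1.38) had a higher score at 30 mg/kg with an unadjusted p under 0.05, as it needs. Adipocyte markers (1.66), which are not markers of this layer, were higher at the same threshold. Enteric neuron and glia markers were higher too, but with an unadjusted p above 0.05. The mean epithelial score, which a larger muscle share should lower, differed by 0.065 (exact permutation p = 0.72), which decides neither way. An effect that grows with dose is not excluded either, as the 10 mg/kg score lay above vehicle by 0.408 with an exact permutation p of 0.222.

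Other splits of the same libraries were counted for each comparison, 100 each with the real one included. For knockout against wild type, 8112 genes were called and at most 5267 in another split, and for anti-p40, 2745 and at most 1. In each, 1 split of 100, the real one, reached the count. This is the smallest share that 100 splits can give, so it argues against chance without excluding it. For 30 mg/kg against vehicle and for 30 against 10 mg/kg, 0 genes were called in edgeR (1004 and 2450 at an unadjusted p under 0.05, 3 and 343 by DESeq2, 0 and 1 by voom). Any split gives at least 0, so that the count (100 of 100, with at most 341 and 200 genes) says nothing about chance. For 10 mg/kg against vehicle 2 of 100 splits reached the 2 genes called, with up to 383 in another, and for the difference between the effects of anti-p40 and 30 mg/kg 2 of 100 splits reached 297, with up to 2277 in another. These shares are under 5% of the splits drawn, without adjustment for the number of comparisons. In both, another split called several times the real count, so that these counts neither exclude chance nor show an effect of the groups by themselves.

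The difference between the anti-p40 and the 30 mg/kg effect passed for 297 genes in a test of the difference itself, in different cohorts. The library with conflicting dose labels had an interferon gamma list level of 4.55 on unscaled log2(CPM + 1), above the wild-type range of 2.29 to 2.5 (vehicle 2.88 to 5.80), and a level of the epithelial response to interleukins 22 and 17 of 5.42, above the wild-type range of 3.59 to 3.98 (vehicle 4.04 to 8.04).

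In 18 of 204 tests, each of 1 score or receptor gene within 1 group, 1 library stood apart from the rest by the gap to its neighbour. Chance gives about 1 in 20, or 10.2, but these tests share libraries and are not independent. Vehicle library 2 scored 4.822 for endothelial adhesion (others 3.652 to 4.036), 5.164 for inflammatory cytokines (2.132 to 3.193), 6.043 for neutrophils (1.658 to 3.808) and 5.567 for matrix metalloproteinases (2.505 to 3.675). Vehicle library 3 scored 3.055 for the interferon gamma list (4.656 to 6.353) and 6.396 for fibroblasts (5.288 to 5.786). At 30 mg/kg, library 8 scored 3.735 for cytokines (1.885 to 2.755), 4.106 for neutrophils (1.138 to 2.559) and 4.052 for metalloproteinases (1.906 to 2.817), library 2 scored 3.046 for tuft cells (1.464 to 2.241) and 7.41 for erythroid markers (1.454 to 2.918), and library 3 scored 3.237 for stem cells (3.746 to 4.175). With anti-p40, library 4 scored 5.904 for hypoxia (6.349 to 6.524), library 5 scored 4.771 for the epithelial response to interleukins 22 and 17 (3.902 to 4.119) and library 2 scored 4.69 for erythroid markers (2.253 to 2.755). In day 77 vehicle, library 3 scored 7.84 for the epithelial response (6.064 to 6.324) and 3.778 for stem cells (4.324 to 4.482), and library 4 scored 7.116 for fibroblasts (6.04 to 6.29).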

How the results depend on the processing

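Leaving out libraries with pancreatic RNA or of low complexity, and each library in turn for the difference between treatment effects, were tests chosen only after the data were seen. No paired analysis was possible because replicate numbers follow only the deposited order. The cause was not tested for any of the changes given here. Of 64 named genes that passed, 620 of 656 other settings were counted as keeping direction and call, and 36 lost the call. The 620 include any DESeq2 fit that kept the direction but gave the gene no adjusted p, and so made no call. With 1 library left out, 1031 of 1060 kept direction and call. Of 38 lists that passed, 137 of 152 settings kept the call, 14 lost it and 1 reversed, and with 1 library left out 122 of 150 kept it and 28 lost it, over 15 of these lists. Of 38 named genes that did not pass, 438 of 467 settings gave the same, 22 passed and 7 reversed, and of 29 such lists 123 of 132, 5 and 4. Small changes were recovered least, with 25.4% of simulated genes at 1.5-fold in the anti-p40 comparison and 13.4% for the difference between effects.

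Counts of called genes stayed within 1.5 times of the main count in 52 of 74 settings. For 30 mg/kg against vehicle (0 in edgeR), DESeq2 called 3 and every other setting 0, also with 1 library left out (0 to 0). For 10 mg/kg (2 in edgeR), DESeq2 called 72, voom 1 (CT010467.1), limma on log2(TPM + 1) 19, on log2(TPM + 0.1) 18 and without a filter 18, and a fit of all 4 first-cohort groups 43. The unassigned library added at its title's dose gave 1 (CT010467.1), libraries without pancreatic RNA 0 and those without low complexity 1 (CT010467.1). In all, 1 to 18 were called with 1 library left out. Between doses (0 in edgeR), DESeq2 called 343, voom 1 (Inhbb), the TPM settings 1, 1 and 1 (Ccdc137, named after its values were seen), a fit of only the 2 groups 17 and of all 4 groups 130, and 0 to 75 with 1 library left out. For anti-p40 (2745), limma on log2(TPM + 0.1) called 1784 and on TPM without a filter 1370, and 1637 to 2523 with 1 library left out. For the difference between effects (297), DESeq2 called 638, voom 1225 and the libraries without pancreatic RNA 116, and 167 to 577 with 1 library left out.

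For knockout against wild type the count of genes stayed between 6656 and 9405, and 7965 genes were shared with DESeq2 and 5449 with limma on log2(TPM + 1). By the median over members, the colonocyte list moved to -0.24 and the goblet cell list to -0.26, and without pancreatic RNA the erythroid list to -0.044. For 10 mg/kg, the endothelial adhesion list was -0.26 by the median over members and the epithelial response to interleukins 22 and 17 was -0.13 without low-complexity libraries. Between doses 2 lists passed by the median over members. With anti-p40, 10 to 15 lists passed with 1 library left out. In the upper range of expression, the correlation of the dose effects was 0.0934 with shared and -0.157 with split vehicle libraries.

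Named genes that changed sign had small effects. In the knockout, Il12a was at -0.081 on TPM without a filter. At 10 mg/kg, Gpr4 ranged from -0.13 (without 10 mg/kg library 6) to 0.21, and Il12b from -0.19 (without library 2) to 0.52, with -0.001 by voom and -0.12 without low-complexity libraries. With anti-p40, Il12a was at 0.10 on log2(TPM + 1) with and without a filter and 0.24 on log2(TPM + 0.1), and ranged from -0.28 to 0.20 with 1 library left out, above 0 without vehicle library 1, 2 or 4 or anti-p40 library 1 or 3. For the difference between effects, Gpr4 ranged from -0.30 to 0.078 (above 0 without 30 mg/kg library 7 or day 77 vehicle library 4), and Il23a was at -0.30 without pancreatic RNA. Between doses, Tmco6, Gm9625 and Pkd2l2 passed without 30 mg/kg library 6 or 9 or 10 mg/kg library 5, Inhbb also without 30 mg/kg library 3 or 10 mg/kg library 2, and Pfdn1 without 30 mg/kg library 9 or 10 mg/kg library 2 (lowest adjusted p 0.0202). Against vehicle, leaving out 10 mg/kg library 6 let Taf15, Gm10925 and Rnaseh2c pass, as did vehicle library 9 for Gm10925 and 10 mg/kg library 2 for Rnaseh2c (adjusted p 0.000933 to 0.0435).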

Other observations

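The tests of gene symbol families and of the genes near Il10 were chosen only after the data were seen. They count genes as independent units, which genes are not, so their p-values do not measure the spread between libraries. Some families of genes with a shared symbol moved together. In the knockout, genes of the major histocompatibility complex (H2-) were higher in 21 of 24 members against 6.30 expected from all genes (Fisher's exact test over families, adjusted p = 9.19e-08), with a median difference of 1.23 by TMM and 1.07 by TPM. The interferon-inducible guanylate-binding proteins (Gbp) were higher in 10 of 10 members (adjusted p = 0.000117, median difference 2.43), as were the proteasome subunits Psmb (10 of 10, adjusted p = 0.000117, 0.53 by TMM and 0.31 by TPM), and the lymphocyte GTPases Gimap in 8 of 8 (adjusted p = 0.0012). Toll-like receptor genes (Tlr), which sense microbial products, were higher in 10 of 12 (adjusted p = 0.00286). Collagen genes (Col) were lower in 25 of 38 members, with 3 higher (adjusted p = 3.05e-05, median difference -0.62), and zinc finger genes (Zfp) were lower in 165 of 359, with 14 higher (adjusted p = 1.84e-14, -0.24 by TMM and -0.36 by TPM). None of the families named changed its direction under RLE or TPM scaling.

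With anti-p40, Gbp genes were lower in 10 of 10 members (adjusted p = 3.98e-09, median difference -1.60), H2- genes in 15 of 24 (adjusted p = 8.44e-09, -1.04), Psmb genes in 7 of 10 (adjusted p = 0.000257, -0.38 by TMM and -0.25 by TPM) and the chemokine genes Cxcl in 6 of 9 (adjusted p = 0.00164, -1.39). Histone genes (Hist) were higher in 17 of 26 members (adjusted p = 4.23e-10, median difference 0.82), although most of their transcripts lack a poly(A) tail and the libraries were made by poly(A) enrichment. Frizzled receptors of Wnt signals (Fzd) were higher in 5 of 9 (adjusted p = 0.0243). These directions were the same under RLE and TPM scaling, and reads shared between members of the H2-, Gbp and Hist families make single members uncertain. In total, 18 of 536 family tests passed in the knockout comparison, 13 of 540 with anti-p40 and 5 of 576 for the difference between effects.

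A segment of another strain around the deleted gene was a further hypothesis, since a knockout is often made in another strain. Of 105 tested genes within 5 Mb of Il10, 46.7% were called in the knockout comparison against 49.4% of the other genes (Fisher's exact test, two-sided, p = 0.625), which argues against a segment that changes many of these genes. With so many genes called elsewhere too, the test could not reveal a segment that changes only a few. All 45 libraries had the Y-linked gene Ddx3y at 33.2 to 63.0 CPM and Xist at no more than 1.378 CPM. The library with conflicting dose labels had list levels on unscaled log2(CPM + 1) of 1.42 for neutrophils, 8.63 for smooth muscle, 5.0 for B cells and 2.04 for proton-sensing receptors. Of the 5 genes with the smallest p between doses, Pkd2l2, Pfdn1 and Tmco6 lie close together on chromosome 18 (from 34408489, 36403676 and 36735039).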
